A study of Mus musculus with 6 samples.

How the data were processed

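Polyadenylated RNA was measured by sequencing in 6 libraries of mouse tailbuds collected at embryonic day 9.5, of which 3 came from wild-type (WT/WT) embryos and 3 from embryos homozygous for the Danforth's short tail mutation (Sd/Sd), all on an outbred CD-1 background. Per the labels' protocols, tailbuds were cut just before the last somite, RNA was extracted with a column kit that included a DNase step, and libraries were made with a stranded mRNA kit. Some libraries hold tailbuds of 2 embryos; which ones is not given in the sources used here. The files deposited by the authors hold raw counts per gene, 1 file per library, listing 37310 Ensembl gene identifiers. Per the submitters' processing notes, the tools named are bcl2fastq 2.17.1.14, CASAVA, STAR 2.5.2b, SAMtools and DESeq2, and the genome build is mm9. The read counter, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned to a strand with certainty.

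Gene symbols were taken from GENCODE M21 on GRCm38, which named 32620 of the 37310 identifiers; identifiers without a symbol held 0.622% of all counts. Because that build differs from the one the authors used, it served only for names, chromosomes and the order of neighbouring genes, and no coordinates are given. All 2269 identifiers on chromosome X, 14 on chromosome Y and 37 of the mitochondrial genome are listed at 0 in every library. The planned comparison of sex between libraries from Xist and Y-linked genes was therefore void, and the share of mitochondrial reads could not be used as a sign of RNA quality.

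Total counts per library were 51936499, 52767718 and 42352598 for WT replicates 1 to 3 and 41788978, 62296689 and 49371420 for Sd/Sd replicates 1 to 3. Between 18761 and 19480 genes had at least 1 count in a library. The gene with the most counts, Eef1a1, took at most 0.923% of a library. Counting intervals and floors given for single genes (95% exact binomial intervals on summed counts, and a floor of 3 counts over the group where a group had 0) cover counting error only, since reads without molecular identifiers are not independent molecules.

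Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 15471 genes holding 99.967% of the counts. Sd/Sd was compared with WT with edgeR 4.0.16 in R 4.3.3 (TMM normalization, robust dispersions, glmQLFit and glmQLFTest, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are given in CPM, counts scaled to a common library size by edgeR's cpm function with TMM factors, as mean ± SD over the 3 libraries of a group. The coefficient of biological variation was 18.6%. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so single genes were judged by the model fitted across genes. Nothing in the labels says that the libraries of a group come from separate litters, so p-values measure the spread between these libraries.

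30 gene lists for tissues and pathways of the tailbud were fixed before the data were examined, as were the design, the rule for named genes and the alternatives unless stated otherwise. The 29 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The sex-linked list had 0 tested members. Each list was also tested with a correlation estimated from the data and with fry, and its members were counted past the threshold over all genes tested and adjusted over the list alone. Genes are named by rule: the tested genes of the Ptf1a locus, Shh, Ptch1, Gli1, Foxa2, T and Noto whatever their result; the up to 10 largest changes in each direction among genes past the threshold with at least 1 CPM in a group and no overlap between groups; and, from each list, up to 4 members past the threshold or else the 2 with the smallest p. Of the genes this rule names, 1 is not reported here as a single gene. Other genes were named after their values were seen, and the text says so.

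Libraries of the same number in both groups deviated together from their group means: over 15471 genes the deviations correlated at 0.194, 0.144 and 0.275 for numbers 1, 2 and 3. WT replicate 1 and Sd replicate 2, of different numbers, correlated at 0.182, above the pair of number 2, and the other 5 pairs of different numbers at -0.330 to 0.0328. All 3 same-number values lie above 0.1, but so does that of WT replicate 1 and Sd replicate 2. Neither the values nor the labels settle whether the numbers pair the libraries. A fit with the replicate number as a block was made only as an alternative beside the unblocked one. No pair of libraries within a group differed by as little as sampling noise, so each counts as 1 replicate.

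Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile normalization, no low-count filter, a stricter filter (1 CPM in 3 libraries), the replicate block, each library left out in turn, removal of sex-linked and haemoglobin genes, dispersions without the robust option, adjusted p thresholds of 0.1 and 0.01, and a test against a fold of 1.2. A covariate for somite gene expression, DESeq2 with the replicate block, and lists without some members were added after seeing the data. The functions were tested on simulated data with 50 genes changed at each size among 15471. Of these, 38% were recovered at 1.5-fold, 62% at 2-fold, 78% at 4-fold and 100% at 8-fold, with 14 false calls. The simulation changed many more genes than the 9 called in the real data, and the adjusted threshold eases as more genes change. These shares therefore do not carry over to the real data. A list lowered 1.5-fold was recovered and 0 of 30 unchanged lists were called. The simulated genes were drawn independently of each other and the lists filled at random. This therefore says nothing on false list calls where members vary together, as in somite derivatives (estimated correlation 0.823) or endothelium (0.610). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.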

Results

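Tailbuds of mouse embryos at embryonic day 9.5 were profiled by polyadenylated RNA sequencing in 3 wild-type (WT) and 3 homozygous Danforth's short tail (Sd/Sd) libraries, with 41788978 to 62296689 counts each. Danforth's short tail is a semidominant mouse mutation, an insertion near the transcription factor gene Ptf1a, that shortens the tail and vertebral column and disturbs the notochord, hindgut and kidneys. The comparison asked which transcripts differ between mutant and wild-type tailbuds and, as the study's title puts forward, how genes of hedgehog signalling behave. Of 15471 genes tested, 6 were higher and 3 were lower in Sd/Sd at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg).

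Ptf1a, a basic helix-loop-helix factor of the pancreas and of inhibitory neurons, was almost silent in WT tailbuds and present in every Sd/Sd library. Ptf1a (ENSMUSG00000026735.2, chromosome 2) measured 0.0521 ± 0.0377 CPM in WT and 18.0 ± 3.65 CPM in Sd/Sd (SD, n = 3 each). Its 8 counts in WT stood against 2671 in Sd/Sd, a ratio of 323 (95% counting interval 164 to 749; edgeR adjusted p = 3.17e-05). Gm13344 (ENSMUSG00000087103.1), a noncoding gene model next but one to Ptf1a, rose with it, from 1 count in WT to 402 in Sd/Sd, a ratio of 389 (69.4 to 15390; edgeR adjusted p = 0.00218). Ptf1a and Gm13344 passed the threshold in all alternatives run.

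The other tested genes around Ptf1a did not pass. Msrb2, a methionine sulfoxide reductase gene 3 places away, had a log2 fold change of 1.12 (SE 0.30, edgeR adjusted p = 1.00), with 2.78 ± 1.11 CPM in WT and 6.01 ± 1.01 CPM in Sd/Sd and no overlap between groups. The log2 fold changes of 4930426L09Rik, Otud1, Pip4k2a and Etl4 were 0.75, 0.32, 0.10 and -0.04. Among 7 tested members of the Ptf1a locus list, 2 rose over all genes tested, and 3, with Msrb2, adjusted over the list alone. The list was higher with the preset correlation (camera adjusted p = 1.60e-09) and had an adjusted p = 0.124 with an estimated correlation. Without Ptf1a and Gm13344, an alternative added after seeing the data, its 5 other members had a median log2 fold change of 0.32 (camera adjusted p = 0.0133; unadjusted p = 0.106 with an estimated correlation). A pair of untested neighbours was looked at after their values were seen: Ptf1aos had 0 counts in WT and 18 in Sd/Sd, at least 5.80-fold higher against a floor of 3 counts over the group, and 1810010K12Rik had 3 and 46, a ratio of 14.8 (4.77 to 74.5). Ptf1aos overlaps Ptf1a on the opposite strand, and since the strand setting of the counting is not given its reads cannot be told from those of Ptf1a.

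**Figure D1:**
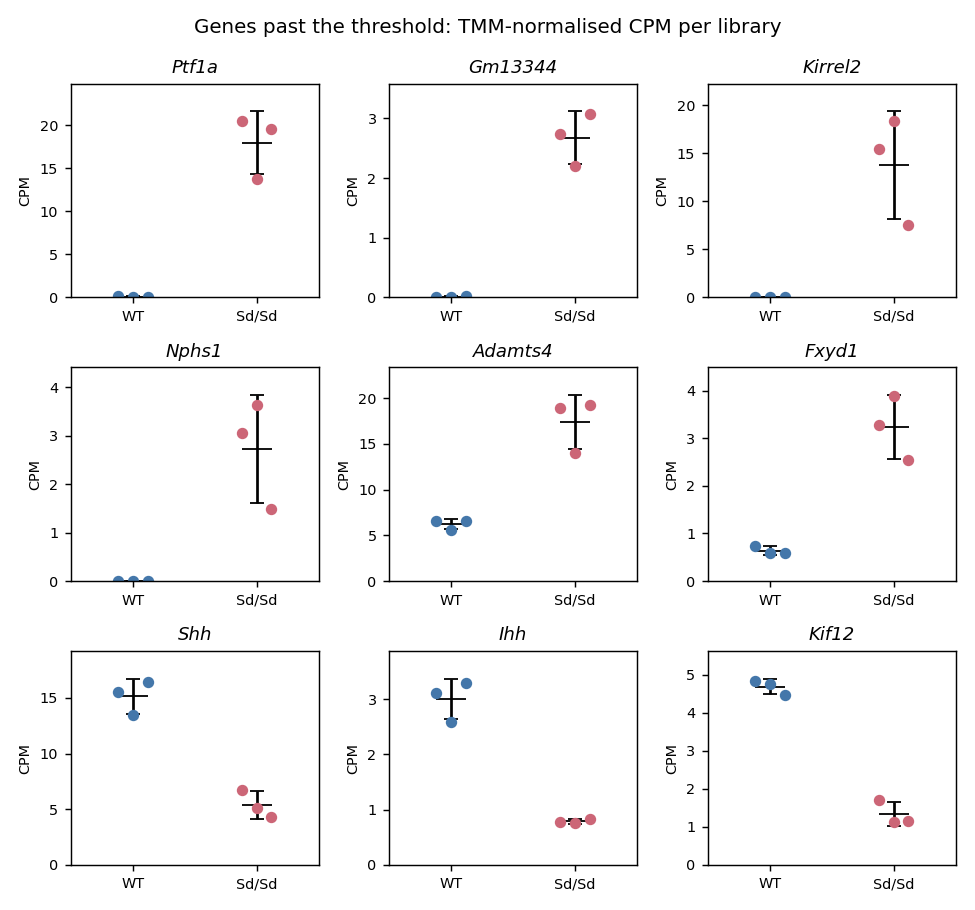
Expression of the 9 genes past the threshold in each library, in TMM-normalised CPM on linear axes from 0. Points are libraries, wide ticks are group means and bars are SD (n = 3); in each panel the 3 Sd/Sd values lie on one side of the 3 WT values.

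Kirrel2 and Nphs1, which encode the immunoglobulin-family adhesion proteins NEPH3 and nephrin and are known targets of Ptf1a in neural tissue, rose in Sd/Sd. They are immediate neighbours on chromosome 7, so the change of Kirrel2 and Nphs1 is not on the chromosome of Ptf1a. Kirrel2 (ENSMUSG00000036915.9) had 1 count in WT and 2149 in Sd/Sd, a ratio of 2078 (95% counting interval 373 to 82107), and reached 13.7 ± 5.59 CPM (SD, n = 3; edgeR adjusted p = 0.00275). Nphs1 (ENSMUSG00000006649.9) had 0 counts in WT and 426 in Sd/Sd, at least 137-fold higher against a floor of 3 counts over the group, and reached 2.72 ± 1.11 CPM (SD, n = 3; edgeR adjusted p = 0.0210). Kirrel2 lost its call without WT replicate 2 (adjusted p = 0.0630), without WT replicate 3 (0.166) and with limma-voom (0.104). Nphs1 lost it without WT replicates 1, 2 and 3 (adjusted p = 0.0738, 0.117 and 0.0560 in turn), without Sd replicate 1 (0.267) and without the robust option (0.0545).

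Most other members of both Ptf1a programs did not pass. Of 17 tested members of the neural program, 2 rose and 15 did not pass; adjusted over the list alone, 2 were higher and 1, Pax2, was lower. The list's median log2 fold change was -0.07 and camera placed it down (adjusted p = 0.785), while its mean was 1.11, a value that depends on the prior count through Kirrel2 and Nphs1. In the pancreatic program 0 of 10 members passed, and 1, Pdx1, was higher adjusted over the list alone (median log2 fold change -0.09, mean 0.42, camera up, adjusted p = 0.503). With fry's test for change in either direction, the adjusted p was 3.66e-05 for the neural and 2.12e-04 for the pancreatic program. This test put 7 lists past the threshold, among them hedgehog pathway components (adjusted p = 4.82e-05) and hindgut (3.66e-05). Pdx1, a pancreatic and duodenal homeobox gene, measured 0.0600 ± 0.0304 CPM in WT and 0.483 ± 0.0473 CPM in Sd/Sd (edgeR adjusted p = 0.316). Cpa1, which encodes pancreatic carboxypeptidase A1, measured 0.786 ± 0.477 and 4.59 ± 3.27 CPM (log2 fold change 2.53, SE 0.81, edgeR adjusted p = 1.00), and passed with the replicate block (adjusted p = 0.0103).

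Shh and Ihh, the genes of the Sonic and Indian hedgehog ligands, fell in Sd/Sd. Shh (ENSMUSG00000002633.3) measured 15.1 ± 1.55 CPM in WT and 5.38 ± 1.25 CPM in Sd/Sd (SD, n = 3), a 2.82-fold lower level (log2 fold change -1.49, SE 0.18, edgeR adjusted p = 0.0438). Ihh (ENSMUSG00000006538.8) measured 3.00 ± 0.363 CPM in WT and 0.788 ± 0.0440 CPM in Sd/Sd, a 3.80-fold lower level (log2 fold change -1.93, SE 0.24, edgeR adjusted p = 0.0438). Both lie close to the threshold and lost the call when any 1 library was left out. Without WT replicates 1, 2 and 3 the adjusted p was 0.263, 0.214 and 0.248 for Shh and 0.317, 0.214 and 0.275 for Ihh. Without Sd replicates 1, 2 and 3 it was 0.0781, 0.157 and 0.0615 for Shh and 0.267, 0.157 and 0.0933 for Ihh. The log2 fold change of Shh stayed between -1.68 and -1.36 in those fits, and that of Ihh between -2.02 and -1.85. Limma-voom gave adjusted p = 0.0860 for Shh and 0.104 for Ihh, and dispersions without the robust option gave 0.0785 and 0.0566.

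Readouts of the pathway did not pass the test. Ptch1, the hedgehog receptor gene that the pathway itself induces, measured 251 ± 4.01 CPM in WT and 199 ± 46.3 CPM in Sd/Sd (log2 fold change -0.34, SE 0.15, edgeR adjusted p = 1.00). Gli1, an induced transcription factor gene, measured 89.8 ± 19.7 and 67.4 ± 24.7 CPM (log2 fold change -0.41, SE 0.34, edgeR adjusted p = 1.00). In Sd/Sd replicates 1, 2 and 3, Ptch1 stood at 253, 175 and 170 CPM and Gli1 at 82.4, 80.9 and 38.9 CPM. Among 24 tested pathway components, 2 fell, Shh and Ihh, over all genes tested and adjusted over the list alone, and 22 did not pass (median log2 fold change 0.04, mean -0.14, camera down, adjusted p = 0.341).

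Notochord genes gave mixed results. Noto, a homeobox gene of the posterior notochord, measured 9.24 ± 1.66 CPM in WT and 1.36 ± 1.09 CPM in Sd/Sd, with no overlap, but did not pass (log2 fold change -2.79, SE 0.86, edgeR adjusted p = 1.00). Its Sd/Sd values were 2.23, 0.144 and 1.71 CPM, and without Sd replicate 2, the lowest, Noto passed (log2 fold change -2.23, adjusted p = 0.0247). Foxa2, a forkhead factor of notochord, floor plate and endoderm, measured 8.06 ± 0.416 and 4.26 ± 1.41 CPM (log2 fold change -0.92, SE 0.23, edgeR adjusted p = 0.930). T, the Brachyury gene of notochord and tailbud mesoderm, measured 160 ± 21.1 and 141 ± 63.2 CPM (log2 fold change -0.18, SE 0.37, edgeR adjusted p = 1.00), and its sign turned without Sd replicate 2 (log2 fold change 0.11). Of 19 tested notochord members 1, Shh, fell over all genes tested, and 3, with Foxa1 and Foxa2, were lower adjusted over the list alone. The list was lower with the preset correlation (median log2 fold change -0.18, camera adjusted p = 0.00133) and had an adjusted p = 0.300 with an estimated correlation. Without the members it shares with the hindgut list, an alternative added after seeing the data, its adjusted p was 0.158 with the preset correlation.

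Floor plate genes, from the ventral midline of the neural tube, had 10 of 12 members with a negative log2 fold change. Shh fell, and 4 members (Shh, Foxa2, Foxa1 and Nkx2-9) were lower adjusted over the list alone. Of these, Shh, Foxa2 and Foxa1 are also on the notochord and hindgut lists, and the floor plate list was not tested without them. The list was lower with the preset correlation (median log2 fold change -0.32, camera adjusted p = 8.99e-05) and had an adjusted p = 0.561 with an estimated correlation. Sd replicate 3 carried most of this: its floor plate score, the mean centred log2 CPM of the members, was -1.02, against -0.03 and 0.05 in Sd replicates 1 and 2 and 0.13 to 0.54 in WT. Without Sd replicate 3 the camera adjusted p was 0.0476 for floor plate and 0.0476 for notochord.

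**Figure D2:**
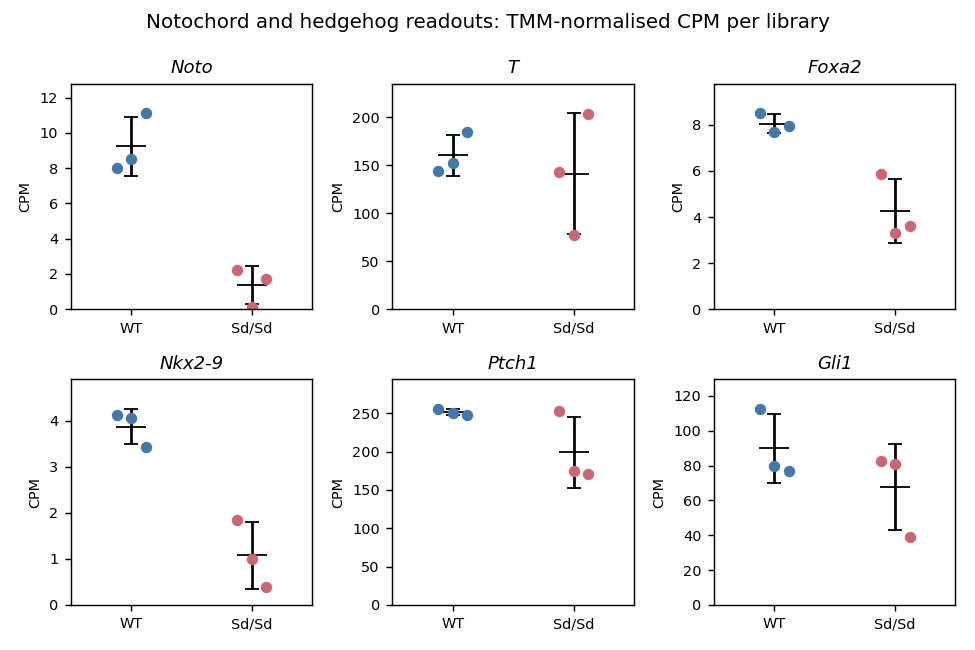
Expression of notochord, floor plate and hedgehog readout genes in each library, in TMM-normalised CPM on linear axes from 0. Points are libraries, wide ticks are group means and bars are SD (n = 3); Noto, Foxa2 and Nkx2-9 do not overlap between groups, while T, Ptch1 and Gli1 do, and these 6 genes did not pass the threshold.

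Hindgut and cloacal endoderm was the list with the smallest camera p. Of its 22 tested members 21 had a negative log2 fold change, with a median of -0.36. Shh and Ihh fell over all genes tested, and 8 were lower adjusted over the list alone, adding Foxa1, Foxa2, Cldn6, Cldn4, Epcam and Vil1. Of these, Cldn6, a tight-junction gene of early epithelia, measured 69.2 ± 4.33 CPM in WT and 48.2 ± 3.54 CPM in Sd/Sd (log2 fold change -0.52, SE 0.08, edgeR adjusted p = 0.173), and Foxa1 measured 13.5 ± 1.88 and 5.54 ± 2.04 CPM (log2 fold change -1.28, SE 0.28, edgeR adjusted p = 0.755); both were chosen after their values were seen. Epcam, an epithelial adhesion gene, measured 43.7 ± 2.93 and 29.8 ± 3.72 CPM (log2 fold change -0.55, SE 0.10, edgeR adjusted p = 0.333). The list was lower with the preset correlation (camera adjusted p = 5.39e-13) and with fry (adjusted p = 0.0251), and had an adjusted p = 0.112 with an estimated correlation (unadjusted p = 0.00385). DESeq2 called Cldn6, Foxa1 and Epcam (adjusted p = 1.83e-04, 8.21e-04 and 0.00435), and so did the fit with the somite covariate that was added after seeing the data. Krt8 and Krt18, keratin genes of the same list named after their values were seen, had log2 fold changes of -0.08 and 0.00.

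Kif12, Adamts4 and Fxyd1 complete the genes past the threshold and belong to none of the fixed lists. Kif12 (ENSMUSG00000028357.6), a kinesin motor gene, fell 3.52-fold, from 4.68 ± 0.201 to 1.33 ± 0.318 CPM (log2 fold change -1.82, SE 0.23, edgeR adjusted p = 0.0481). Adamts4 (ENSMUSG00000006403.6), which encodes a metalloproteinase that cleaves aggrecan, rose 2.78-fold, from 6.26 ± 0.537 to 17.4 ± 2.94 CPM (log2 fold change 1.47, SE 0.16, edgeR adjusted p = 0.0210). Fxyd1 (ENSMUSG00000036570.7), which encodes phospholemman, a regulator of the sodium-potassium pump, rose 5.04-fold, from 0.639 ± 0.0868 to 3.24 ± 0.666 CPM (log2 fold change 2.33, SE 0.27, edgeR adjusted p = 0.0330). Kif12 lost its call with the stricter filter (adjusted p = 0.0538) and whichever library was left out, at 0.322, 0.372 and 0.248 without WT replicates 1, 2 and 3 and 0.103, 0.157 and 0.103 without Sd replicates 1, 2 and 3. Adamts4 kept its call only without Sd replicate 2 (adjusted p = 0.00581); without WT replicates 1, 2 and 3 its adjusted p was 0.166, 0.214 and 0.133, and without Sd replicates 1 and 3 it was 0.231 and 0.0514. Fxyd1 kept its call only without Sd replicate 3 (adjusted p = 0.0315); without WT replicates 1, 2 and 3 its adjusted p was 0.181, 0.300 and 0.243, and without Sd replicates 1 and 2 it was 0.236 and 0.115. Limma-voom and dispersions without the robust option gave 0.0860 and 0.0785 for Kif12, 0.104 and 0.0545 for Adamts4, and 0.107 and 0.0545 for Fxyd1. DESeq2 called 34 genes, all 9 of these and 25 more, of which 13 were higher and 12 lower; limma-voom called 3.

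Targets that hedgehog signalling activates had 17 of 24 members with a negative log2 fold change and 0 past the threshold. Nkx2-9, a homeobox gene of the ventral neural tube, measured 3.88 ± 0.386 CPM in WT and 1.08 ± 0.731 CPM in Sd/Sd (log2 fold change -1.86, SE 0.47, edgeR adjusted p = 1.00), without overlap; DESeq2 called Nkx2-9 (adjusted p = 0.0160). The target list was lower with the preset correlation (median log2 fold change -0.19, camera adjusted p = 3.93e-04) and had an adjusted p = 0.561 with an estimated correlation. Ventral neural tube genes had 9 of 14 members negative and 0 past (median log2 fold change -0.29, camera adjusted p = 0.0133), and intermediate mesoderm and nephric duct genes 12 of 16 negative and 0 past (median -0.27, camera adjusted p = 0.00133); both had an adjusted p = 0.561 with an estimated correlation. Pax2 and Ret, nephric genes of the last list, measured 11.4 ± 0.276 against 7.82 ± 0.855 CPM and 50.3 ± 1.59 against 38.5 ± 5.17 CPM, and both were lower adjusted over the list alone. Lhx3, a motor neuron gene, had a log2 fold change of -1.13 (SE 0.51, edgeR adjusted p = 1.00). All 3 lists rested on Sd replicate 3: without it, the camera adjusted p was 0.834 for the hedgehog targets, 0.834 for intermediate mesoderm and 0.898, with the direction turned, for the ventral neural tube. Ventral neural tube genes also lost the call without WT replicate 1 (adjusted p = 0.150).

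Sd replicate 3 stood apart in genes of somites and neural tube. Its somite list score, the mean centred log2 CPM of the members, was -2.19, against -0.49 to 1.27 in the other libraries, and its dorsal neural score was -1.15, against -0.43 to 1.02. Its hedgehog target score was -1.39, against -0.14 to 0.48 elsewhere. The first principal component, 33.8% of the variance, separated Sd replicate 3 from Sd replicate 2 at its ends and not the genotypes. The hindgut score, in contrast, was between -0.33 and -0.22 in the 3 Sd/Sd libraries and between 0.14 and 0.34 in the 3 WT libraries. Separation of the groups was not particular to hindgut. Among other lists, the notochord score was -0.42 to -0.12 in Sd/Sd and 0.22 to 0.24 in WT. The floor plate score was -1.02 to 0.05 and 0.13 to 0.54. Both lists share Shh, Foxa1 and Foxa2 with hindgut. By small gaps, the BMP signalling score (-0.092 to 0.024 in Sd/Sd, 0.030 to 0.063 in WT) and the limb bud score (-0.051 to -0.029 and -0.023 to 0.131) also separated. BMP signalling and limb bud each had a camera adjusted p = 0.385, so separation of scores alone does not mark a changed list.

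**Figure D3:**
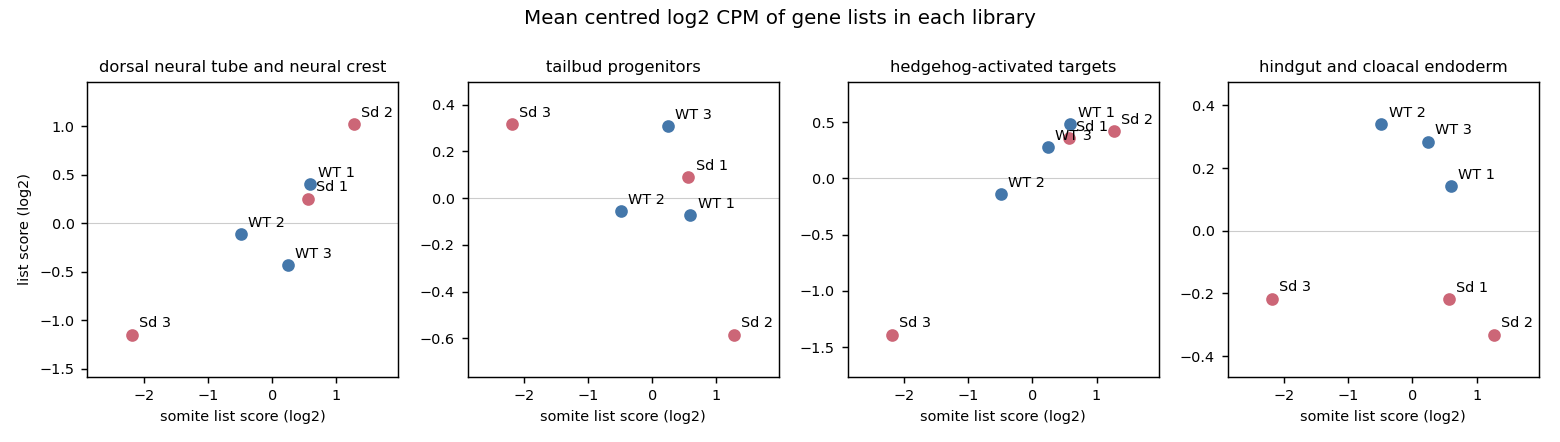
Scores of 4 gene lists (mean centred log2 CPM of the members, vertical axes) against the somite list score (horizontal axes) in each of the 6 libraries, WT in blue and Sd/Sd in red. Sd replicate 3 has the lowest somite, dorsal neural and hedgehog target scores (-2.19, -1.15 and -1.39), while the hindgut score separates the groups.

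Further lists that were lower with the preset correlation had 0 members past the threshold. Visceral yolk sac endoderm genes had 7 of 8 members negative (median log2 fold change -0.67, camera adjusted p = 0.00222; adjusted p = 0.300 with an estimated correlation); its apolipoprotein genes Apob and Apoa1 had log2 fold changes of -1.02 (SE 0.36) and -1.28 (SE 0.51) at 0.574 and 0.139 CPM in Sd/Sd. Endothelium had 15 of 16 members negative (median -0.16, camera adjusted p = 4.80e-04; adjusted p = 0.561 with an estimated correlation), with Sox18 at -0.26 (SE 0.10) and Emcn at -0.30 (SE 0.15), and lost the call without Sd replicate 1 (adjusted p = 0.0764) or 2 (0.0857). Surface ectoderm had 14 of 19 negative (median -0.10, camera adjusted p = 0.0342; adjusted p = 0.561 with an estimated correlation), with Epcam lower adjusted over the list alone and Esrp1, a splicing factor gene of epithelia, at -0.30 (SE 0.09). Surface ectoderm lost the call without WT replicate 2 (adjusted p = 0.259), Sd replicate 1 (0.312) or Sd replicate 2 (0.0780).

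Markers of progenitors, segmentation and other tissues gave no list past the threshold and 0 members past it. Tailbud progenitor genes had a median log2 fold change of -0.03 (camera adjusted p = 0.305; Sp5 -0.56, Cdx1 -0.32), and segmentation clock and Notch genes -0.03 (adjusted p = 0.823; Lfng 0.41, Hey1 -0.10). Somite derivatives had a median of 0.24 and a mean of 0.32 while camera placed them down (adjusted p = 0.489), with Pax1 at 1.91 (SE 2.16) and Scx at -0.40. Dorsal neural tube and neural crest genes had a median of 0.17 (adjusted p = 0.421), with Sox8 at 0.97 (SE 0.23) higher adjusted over the list alone and called by DESeq2 (adjusted p = 0.0298), and Msx3 at 1.62 (SE 0.99). Posterior Hox genes had a median of -0.20 (adjusted p = 0.0880; Hoxa10 -0.26, Hoxd13 -0.31) and passed with the replicate block (adjusted p = 0.0303), with an adjusted p = 0.561 with an estimated correlation and no block. Retinoic acid genes stood at -0.01 (adjusted p = 0.516; Aldh1a3 -1.23, Cyp26b1 -0.37), BMP signalling at -0.01 (0.385; Smad6 -0.24, Id3 0.23), and limb bud and lateral plate mesoderm at -0.04 (0.385; Foxf2 -0.58, Tbx3 -0.32). Single libraries decided several of these: somite derivatives were lower without Sd replicate 2 (adjusted p = 0.00277) and higher without Sd replicate 3 (9.28e-07), and dorsal neural genes were higher without Sd replicate 3 (0.00578), each with the preset correlation. With an estimated correlation over all 6 libraries (0.823 for somite and 0.187 for dorsal neural genes) their adjusted p was 0.863 and 0.831. Tailbud progenitor genes were lower without Sd replicate 1 (0.0489) or 3 (0.00299) and higher without Sd replicate 2 (0.00955), against an adjusted p = 0.831 with an estimated correlation over all 6 libraries. Posterior Hox genes were lower without WT replicate 3 (0.0262) or Sd replicate 1 (0.0313).

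Cell state and blood lists did not pass either, with 0 members past the threshold. Proliferation genes had a median log2 fold change of 0.03 (camera adjusted p = 0.170; Ccne2 -0.24, Mcm6 0.12), p53 targets and cell death genes 0.00 (0.556; Cdkn1a -0.42, Tnfrsf10b -0.29), and hypoxia genes -0.01 (0.385; Vegfa -0.46, Car9 -0.74). Primitive erythroid genes had 12 of 12 members negative (median -0.22, adjusted p = 0.107; Hemgn -0.35) and passed with the replicate block (adjusted p = 6.57e-04), while their score was -1.28 in Sd replicate 1 and 1.09 in Sd replicate 2. Their estimated correlation was 0.977, and with it and no block the adjusted p was 0.831. Immediate early and heat shock genes had 12 of 13 negative (median -0.13, adjusted p = 0.102; Jun -0.24, Dusp1 -0.20) and passed with the block (adjusted p = 0.0281), with an adjusted p = 0.719 with an estimated correlation and no block. Macrophage genes had a median of -0.09 and a mean of 0.03 (adjusted p = 0.787; Fcer1g 0.55, Cd68 -0.23), neuronal genes -0.11 and 0.03 (0.528; Stmn4 -0.68, Map2 -0.22), with camera down for both, and primordial germ cell genes a median of -0.08 (0.170; Nanos3 -0.40, Dppa4 -0.63). Erythroid genes were lower without Sd replicate 2, the library richest in them (adjusted p = 4.82e-07).

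**Figure D4:**
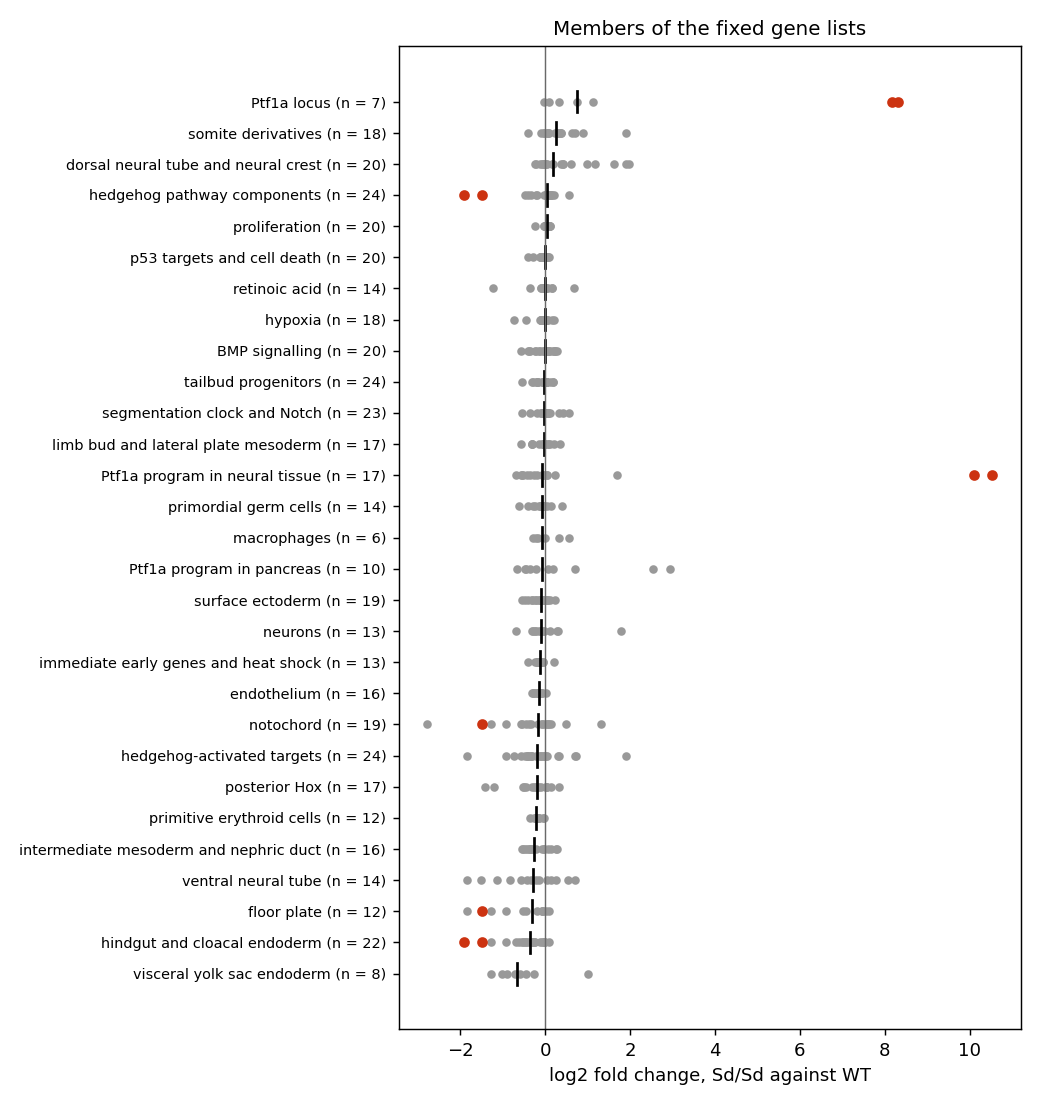
Log2 fold changes of Sd/Sd against WT (horizontal axis) for the tested members of the 29 fixed gene lists, sorted by median. Grey points did not pass, red points passed an adjusted p of 0.05, and black bars mark list medians; fitted values of genes with 0 or 1 count in WT, such as Nphs1 and Kirrel2, depend on the prior count, and hindgut genes lie to the left of 0 in 21 of 22 cases.

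Across the lists, camera with the preset correlation placed 1 list higher and 9 lower. Fry placed 2 past the threshold for a common direction (Ptf1a locus and hindgut) and 7 for change in either direction. With an estimated correlation in camera 0 passed after adjustment, and 4 had an unadjusted p under 0.05. The replicate block changed the count of lists from 10 to 13. Across single genes, 448 of 15471 had an unadjusted p under 0.05 (edgeR), of which 146 were higher and 302 lower. That is a smaller share than the 0.05 expected if no gene differed, so the count by itself does not show a broad change. The groups did not overlap in 7.68% of genes, against 10% by chance for 3 against 3.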

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

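The fits with the somite score as covariate, DESeq2 with the replicate block, and lists without some members were chosen only after the results were seen. The cause of a change was not tested unless stated. The 9 genes (6 higher, 3 lower) became 34 (19 and 15) with DESeq2, 3 (3 and 0) with limma-voom, where 497 genes had an unadjusted p under 0.05, 14 (5 lower) without a low-count filter, 3 (3 and 0) without the robust option, where 455 had one, and 3 (3 and 0) at an adjusted p of 0.01, 16 (8 lower) with the covariate and 52 (23 and 29) with DESeq2 and the block, which called Msrb2, Foxa2, Cpa1, Sox8, Nkx2-9, Epcam, Vegfa and Aldh1a3 among the named genes. A test against a fold of 1.2 left 0 lower genes and 6 in all, by its construction. With 1 library left out, which leaves fewer samples, 4, 2 and 3 genes passed without WT replicates 1, 2 and 3 and 3, 6 and 5 without Sd replicates 1, 2 and 3, of which 2 to 5 were higher and 0 to 1 lower. Of the 7 genes fixed for a separate look, 2 passed (Ptf1a and Shh), 1 with limma-voom or without the robust option, and 1 to 2 with a library left out. RLE and upper-quartile scaling, and removal of haemoglobin genes, kept 9 genes, all shared. The replicate block gave 12 genes, adding Cpa1, and Cacna1g and Capn1, chosen after their values were seen, and changed no other call besides the lists named here. Over 62 named genes and the alternatives other than DESeq2 with the block, the test against a fold and the other thresholds, for which calls were only counted, 921 results kept direction and side of the threshold, 47 lost the call, 6 gained it and 6 turned direction without a call. The last were Etl4 (log2 fold change -0.10 to 0.064), T (-0.54 to 0.11) and Hemgn (-1.33 to 0.16) with a library left out, and Pax1 with the covariate (-0.16). The 10 lists became 0 with an estimated correlation and 2 with fry. Adjusted p with an estimated correlation was 0.112 for hindgut, 0.124 for the Ptf1a locus, 0.300 for notochord and yolk sac, and 0.561 for endothelium, floor plate, hedgehog targets, intermediate mesoderm, surface ectoderm and ventral neural tube. With fry it was 0.216 for notochord and yolk sac, 0.364 for floor plate and surface ectoderm, and 0.576 for endothelium, hedgehog targets, intermediate mesoderm and ventral neural tube; the neural Ptf1a program turned up (0.364). The block added posterior Hox (0.0303), erythroid (6.57e-04) and immediate early genes (0.0281), the last also passing with the stricter filter (0.0337), under which the pancreatic program turned down (0.277). The covariate turned segmentation genes (0.940) and called tailbud progenitors (0.0388; unadjusted p = 0.571 with an estimated correlation of 0.748), and notochord without hindgut members had 0.158. Of the results for lists, 273 kept direction and side, 27 lost the call, 21 gained it and 28 turned, of which 2 had an adjusted p under 0.05, both with a library left out: somite derivatives without Sd replicate 3 (9.28e-07) and tailbud progenitors without Sd replicate 2 (0.00955). With a library left out the adjusted p ran from 1.18e-09 to 0.0857 for endothelium, 2.68e-08 to 0.834 for hedgehog targets, 5.82e-05 to 0.834 for intermediate mesoderm, 0.00857 to 0.312 for surface ectoderm and 0.00455 to 0.898 for ventral neural tube. Of lists not past the threshold, it ran from 0.00578 to 0.734 for dorsal neural tube, 0.0525 to 0.798 for hedgehog components, 0.00729 to 0.906 for hypoxia, 0.0230 to 0.769 for immediate early genes, 0.209 to 0.991 for macrophages, 0.0594 to 0.991 for neurons, 0.410 to 0.977 for p53 targets, 0.0262 to 0.741 for posterior Hox, 4.82e-07 to 0.771 for erythroid cells, 0.0426 to 0.783 for germ cells, 0.336 to 0.981 and 0.373 to 0.878 for the neural and pancreatic Ptf1a programs, 0.0795 to 0.991 for retinoic acid, 0.0117 to 0.991 for segmentation, 9.28e-07 to 0.991 for somite derivatives and 0.00299 to 0.779 for tailbud progenitors. Calls that these lists gained were, without WT replicate 1, hypoxia (0.00729), immediate early (0.0230) and erythroid genes (0.0406); without WT replicate 2, germ cells (0.0426); without WT replicate 3, immediate early (0.0330), posterior Hox (0.0262) and erythroid genes (0.0474); without Sd replicate 1, posterior Hox (0.0313), segmentation (0.0117) and tailbud progenitors (0.0489); without Sd replicate 2, immediate early genes (0.0385), erythroid cells (4.82e-07), somite derivatives (0.00277) and tailbud progenitors (0.00955); and without Sd replicate 3, dorsal neural tube (0.00578), hypoxia (0.0152), somite derivatives (9.28e-07) and tailbud progenitors (0.00299). Depth limits what can be said of Gm13344, Kirrel2 and Nphs1 in WT, where 0 or 1 count was seen, to a ratio or bound.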

Other observations

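The tests of the somite score, of sequencing depth, of the amount of endoderm, of the hedgehog targets in Sd replicate 3, and of wild-type or heterozygous tissue in Sd replicate 1 were chosen only after the result was seen, and the lists of arterial, venous, contractile and interferon genes were added after single genes had been seen, with the genes named here chosen for their values. Arterial endothelial genes tended lower in Sd/Sd. Gja5, a gap junction gene of arteries, measured 30.1 ± 3.09 CPM in WT and 19.5 ± 2.95 CPM in Sd/Sd (log2 fold change -0.63, SE 0.13, edgeR adjusted p = 0.542; DESeq2 adjusted p = 0.00718), and Dll4, a Notch ligand of arteries, 16.1 ± 2.00 and 10.7 ± 1.81 CPM (log2 fold change -0.59, SE 0.16). Without Gja5, Dll4 and Notch4, which prompted the list, 11 of 12 members were lower (median log2 fold change -0.14), with p = 0.0307 with an estimated correlation, not adjusted over the 4 lists added. This is consistent with a hypothesis of reduced arterial identity, but the general endothelium list had a median of -0.16, so fewer endothelial cells may account for it as well. Venous genes had p = 0.393 with an estimated correlation, and the difference between arterial and venous genes was not tested.

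Contractile genes and interferon-stimulated genes were less clear. Without Cnn1, Des, Actc1, Tagln and Myl9, which prompted the list, 11 of 12 contractile genes were lower, with p = 0.289 with an estimated correlation. Isg15 measured 0.152, 0.341 and 0.142 CPM in WT and 1.31, 0.607 and 2.06 CPM in Sd/Sd (log2 fold change 2.61, SE 0.56, edgeR adjusted p = 0.566; DESeq2 adjusted p = 0.0191). Without Isg15 and Usp18, 12 of 18 interferon-stimulated genes were higher, with p = 0.120 with an estimated correlation. A reduced smooth muscle program and an interferon response both stay open hypotheses on these values.

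The hindgut list had the smallest camera p of the fixed lists (adjusted p = 5.39e-13 with the preset correlation), but did not pass with an estimated correlation (adjusted p = 0.112, unadjusted p = 0.00385). A carry-over from genes shared with notochord and floor plate is argued against, since without them 16 of 17 members were still lower (camera unadjusted p = 0.00780 with an estimated correlation). With the somite score as covariate the camera adjusted p was 2.58e-13 with the preset correlation (unadjusted p = 0.0146 with an estimated correlation). The somite score overlapped between groups (-0.485 to 0.594 in WT, -2.19 to 1.27 in Sd/Sd), so this covariate could remove little of a genotype difference. The hindgut score was low in the Sd/Sd libraries with the highest and the lowest somite score (-0.33 and -0.22). This argues against somite-level tissue as the source, but the somite score does not measure how much hindgut the dissections held. Fewer endoderm cells in the Sd/Sd dissections would lower endoderm genes alike, yet the 11 members on no other list had a median log2 fold change of -0.31, 1.61 above that of Ihh at -1.93. Ihh was 1 of the 2 members past the threshold in these data, so a gap to the median follows in part from that choice. The gap therefore does not show that Ihh fell beyond a loss of cells. Claudin, keratin and adhesion genes are also made outside the endoderm, which would dilute their change. A loss of cells and lower expression per cell cannot be told apart here. The design confounds both with genotype.

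The main axis between libraries followed somite and dorsal neural genes, not genotype: over 6 libraries the first component and the somite score correlated at Pearson r = -0.895 (exact permutation p = 0.0153, adjusted 0.0255; Spearman rho = -0.943, p = 0.0167), and at -0.916 without the 2 libraries farthest from the median. The somite and dorsal neural scores correlated at r = 0.915 (exact permutation p = 0.00972) and rho = 0.943 (p = 0.0167), with adjusted p of 0.0243 and 0.0278 over 5 relations, and at r = 0.960 without the 2 farthest. The somite and tailbud progenitor scores correlated at r = -0.657 (exact permutation p = 0.161, adjusted 0.201; rho = -0.829, p = 0.0583; r = -0.989 without the 2 farthest). A candidate explanation is that dissections reached to different levels along the trunk, since the tailbud was cut near the last somite. Sequencing depth stays open as a further source: the first component and the total count correlated at r = -0.511 (exact permutation p = 0.307; rho = -0.486, p = 0.356; r = -0.408 without the 2 farthest).

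The lower hedgehog target list rested on Sd replicate 3, whose target and somite scores were both the lowest; over 6 libraries these scores correlated at r = 0.966 (exact permutation p = 0.00694, adjusted 0.0243; rho = 0.943, p = 0.0167), but at 0.570 without the 2 farthest libraries, so the relation rests on those. With the somite score as covariate the list was still lower with the preset correlation (adjusted p = 5.95e-04), but with an estimated correlation (0.181), a test added after that value was seen, p was 0.154 with the covariate and 0.213 without it, so neither value decides and tissue amount stays open. Shh in Sd replicate 3 was 0.727 of the mean of the other Sd/Sd libraries, which neither shows nor excludes a deeper loss of Shh there. An earlier look had asked instead whether targets were less reduced in Sd replicate 1. The values argue against wild-type or heterozygous tissue in it, since the median ratio of Ptf1a, Gm13344, Kirrel2 and Nphs1 to the other Sd/Sd libraries was 1.19, and against more somite tissue, since its somite score minus the highest of the others was -0.711; the question on Sd replicate 3 replaced that one.

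Other splits of the 6 libraries were compared with the genotypes. The real split gave 9 genes and the highest of the other splits gave 1; the real split was 1 of 10 with a count as large, and 10 splits are too few for a share under 0.05. For gene lists with the preset correlation the real split gave 10, the highest other 12, and 4 of the 10 splits gave as many as the real one. Among the 4 splits that part all 3 numbered pairs, the others gave at most 0 genes and 11 lists; the 6 remaining splits part 1 pair and gave at most 1 gene and 12 lists. At an unadjusted p under 0.05 (edgeR) the genotypes gave 448 genes of 15471, a smaller share than the 0.05 expected if no gene differed. Other splits gave 1960, 1424, 666, 568, 470 and 459, above the genotypes, and 392, 327 and 290, below them. The largest of these counts point to a structure of the libraries apart from genotype.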
